A study of Mus musculus with 12 samples.

How the data were processed

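RNA sequencing libraries of 6 cell populations sorted from the back skin of CD1 mice at postnatal day 5 were analysed. Dermal sheath, dermal papilla, dermal fibroblasts, outer root sheath, matrix and melanocytes had 2 libraries each. The sort gates and markers of each population are not stated in the sources used here. Per the labels, total RNA with an integrity number of at least 8 was isolated with the Absolutely RNA Nanoprep kit, 6 ng of it was amplified with the Ovation RNA-seq V2 system, and 100 ng of cDNA entered library preparation.

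The deposited table holds 1 column of FPKM (read coverage scaled to transcript length and library size) per library, made by the authors, and per the submitters' processing notes TopHat2 2.0.3, Bowtie2, Cufflinks 2.1.1 and genome build mm10 were used. The role and order of these tools, the annotation and any filter are not stated in the sources used here. The unit was inferred from the tool named and from the values, which are not whole, are never negative and differ in sum between columns. Whole read counts could not be recovered from the low values (at most 3.55% of them fell on any 1 step), so the depth of each library is unknown and precision is given only as the spread between the 2 libraries. The table has 19150 genes, with 15 repeated symbols and 119 entries that carry several symbols, and 707 genes are at 0 in all 6 dermal libraries. Gene coordinates are those of GENCODE M21 on mm10.

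FPKM were analysed as log2(FPKM + 1) without further scaling. The median log2 difference over all tested genes was -0.02 for sheath minus fibroblasts, -0.09 for sheath minus papilla and 0.06 for papilla minus fibroblasts. Genes with at least 1 FPKM in at least 2 of the 6 dermal libraries were tested (13219 genes, 5931 not tested). The 6 libraries entered 1 fit in limma 3.58.1 (R 4.3.3) with an intensity trend in the prior variance and 3 residual degrees of freedom. All p-values are two-sided with Benjamini-Hochberg adjustment within a comparison, and a gene was called where the adjusted p was under 0.05 and the absolute log2 difference at least 1. Genes higher in 1 population than in both others are those called in both comparisons. Their number is given beside the number for independent lists of the same sizes and beside 100 simulations of unchanged groups that share libraries in the same way. Outer root sheath, matrix and melanocyte libraries entered no test among the dermal populations.

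Gene lists were compared with camera in limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists within a comparison. Of 29 lists (551 entries, 529 distinct genes, 12 of them not in the table), 27 had at least 5 tested members and were tested. The result of 1 list is not reported here. The others were contractile machinery, calcium handling, vasoactive receptors, dermal papilla genes, dermal fibroblast genes, fibrillar matrix, basement membrane, integrins and focal adhesion, BMP, WNT, FGF, hedgehog, TGF-beta, Notch, and IGF and PDGF signalling, cell cycle, and immediate early genes. Lists of other cell types were basal keratinocyte, hair matrix and shaft, melanocyte, endothelial, pericyte, Schwann cell, macrophage, mast cell and lymphocyte, adipocyte, skeletal muscle and erythroid. Members of a list were also counted with adjusted p-values computed over the list alone. The dermal papilla list shares Bmp4, Bmp6, Nog and Sostdc1 with the BMP list, and Fgf7 and Fgf10 with the FGF list. It shares Wif1, Notum, Rspo2, Rspo3, Lef1 and Wnt5a with the WNT list. Hhip (hedgehog), Hey1 (Notch), Inhba (TGF-beta) and Igfbp3 (IGF and PDGF) are shared as well. Results of these signalling lists are therefore not independent of the papilla list.

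The comparisons, lists, thresholds and the rule for naming genes were fixed before the data were examined. Named genes are, for each comparison and direction, the 5 called genes with the largest absolute log2 difference, a mean of at least 5 FPKM in the higher group and no overlap between libraries. For each set higher in 1 population than in both others, they are the 10 with the largest smaller log2 difference and at least 5 FPKM, and for each list described up to 4 called members with the largest absolute log2 difference. Acta2, Itga8, Myh11, Tagln, Mylk, Sox2, Lef1, Alpl, Corin, Pdgfra, Pdgfrb, Lum, Dcn, Ednra and Ednrb are named whatever their values. The set shared by sheath and papilla against fibroblasts, the comparison of outer root sheath and matrix, and a few genes marked in the text were added after the data were seen.

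The test was run on simulated data with 50 genes changed at each fold. Changed genes were drawn only from well expressed ones, and noise was independent between libraries, without the deviations shared by replicate number. The shares of genes called therefore hold for such genes and such noise only. For sheath against fibroblasts (12762 genes tested), 22%, 84%, 94% and 98% of genes changed 2, 3, 4 and 8-fold were called, with 7 false calls. For sheath against papilla (12772 genes) the shares were 12%, 74%, 96% and 100% with 18 false calls, and for papilla against fibroblasts (12761 genes) 18%, 76%, 94% and 100% with 9 false calls.

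Alternatives fixed before the data were examined were a pseudocount of 0.1 or 5, no filter on low values, a filter of at least 5 FPKM, quantile normalization, scaling to the median log ratio, a replicate block, each pair fitted alone, no intensity trend, robust empirical Bayes, adjusted p alone, all 6 populations in the fit, and leaving out each dermal library in turn. For lists they were camera with an estimated correlation, fry, quantile normalization and a pseudocount of 0.1. A planned count test was not run because whole reads could not be recovered. Alternatives chosen after the data were seen left out short RNAs and genes listed at 0 in both libraries of a dermal population, left out genes at least as high in melanocytes as in fibroblasts, or subtracted melanocyte RNA from each fibroblast library at the median share of 11 pigment cell markers (37.2% and 51.8%), with values below 0 set to 0 and the rest divided by 1 minus that share. Each fibroblast library was paired with the melanocyte library of the same number. Both shares exceeded the median ratio (26.9%) of 19 other genes restricted to melanocytes, so the subtraction tends to overcorrect such genes. A replicate block for the lists was also added after the data were seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.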

Results

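Gene expression was measured by RNA sequencing in 6 cell populations sorted from the back skin of CD1 mice, an outbred strain, at postnatal day 5. Hair follicles are growing at this age. The dermal sheath is the layer of mesenchymal cells that wraps the follicle, the dermal papilla is the mesenchymal cluster at its base that signals to the epithelium, and dermal fibroblasts lie between follicles. The outer root sheath and the matrix are epithelial compartments of the follicle, and melanocytes are its pigment cells. Each population was represented by 2 libraries, 12 in all, and the comparisons were made among the 6 libraries of the 3 dermal populations. The series concerns contraction of the dermal sheath in the regression of the hair follicle, so the comparisons ask which genes, contractile ones among them, set the sheath apart from the papilla and from other fibroblasts. Whether any named gene, Acta2 among them, was used to sort the cells is not stated in the sources used here. A difference in such a gene would be set by the sort.

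Values were FPKM, a measure of read coverage per transcript length and library size, for 19150 genes, of which 13219 passed the filter and were tested. The FPKM of a library summed to between 373066 (outer root sheath replicate 2) and 524040 (dermal sheath replicate 1), and between 10951 and 12413 genes reached 1 FPKM. The files give no read counts, so the depth behind each value is unknown. The median SD between the 2 libraries of a population was 0.27 on the log2 scale in dermal sheath, and 0.25 in both dermal papilla and dermal fibroblasts. No label says that the 2 libraries of a population came from separate animals. P-values of single genes therefore measure the spread between these libraries, which may be technical. Camera p-values at the preset correlation set list members against the other tested genes, so they do not measure spread between animals. Levels are given as mean FPKM ± SD (n = 2), differences as log2 ± SE, and each fold is on the log2(FPKM + 1) scale, which understates changes of weakly expressed genes. Adjusted p-values came from limma with Benjamini-Hochberg adjustment.

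Dermal sheath cells expressed Acta2, Actg2 and Casq2 far above dermal fibroblasts. Acta2 (chromosome 19, 34241090 to 34255590), which encodes smooth muscle alpha-actin, reached 1069.7 ± 440.4 FPKM in dermal sheath against 6.87 ± 1.30 in fibroblasts, a 131-fold difference (log2 7.03 ± 0.36, adjusted p = 2.31e-05). Actg2 (chromosome 6, 83512905 to 83536265), the enteric smooth muscle gamma-actin, stood at 362 ± 7.22 against 1.34 ± 0.175 FPKM, 155-fold higher (adjusted p = 4.32e-06). Casq2 (chromosome 3, 102086415 to 102146514), the cardiac calsequestrin that stores calcium in the sarcoplasmic reticulum, was 106-fold higher at 185 ± 34.2 FPKM (adjusted p = 1.39e-05). In the other direction, fibroblasts held more of Lum (chromosome 10, 97565128 to 97572703), a collagen-binding proteoglycan, at 759 ± 284 against 71.6 ± 29.0 FPKM, 10.5-fold higher than in sheath (log2 sheath minus fibroblasts -3.40 ± 0.35, adjusted p = 0.000555).

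**Figure D1:**
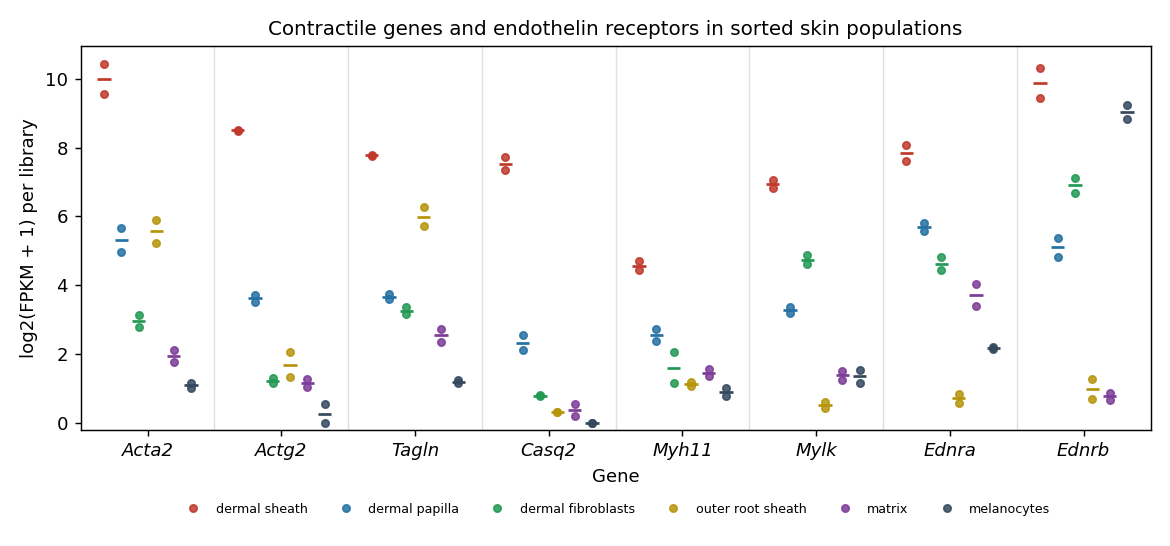
Log2(FPKM + 1) of contractile genes and endothelin receptors in each library of the 6 sorted populations. Points are libraries and short lines are means of 2 libraries. Acta2 was 131-fold higher in dermal sheath than in dermal fibroblasts and 25.8-fold higher than in dermal papilla. Ednrb was also high in melanocytes (529.8 ± 102 FPKM).

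In all, 999 genes were higher and 873 lower in dermal sheath than in dermal fibroblasts among those tested. Without 1 of the fibroblast libraries, 442 (without replicate 1) or 422 (without replicate 2) genes were higher in fibroblasts, and a pseudocount of 5 gave 658 and 442 genes. Fits without 1 library have fewer degrees of freedom and lose calls at similar folds too. With melanocyte RNA subtracted from the fibroblast libraries, 1795 genes were higher in sheath, and with genes at least as high in melanocytes as in fibroblasts left out before the fit 417 were higher in fibroblasts. The fibroblast libraries also held pigment cell transcripts, and 472 of the 873 genes (54.1%) were at least as high in the melanocyte libraries as in fibroblasts, against 51.1% of all tested genes.

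Of the 22 tested genes of the contractile machinery list, 16 were higher in sheath, 1 was lower and 5 were not called, with the same counts adjusted over the list alone (camera adjusted p = 3.13e-13, and adjusted p = 0.0477 with an estimated correlation). Tagln, an actin-binding protein of smooth muscle, was 23.0-fold higher at 218 ± 4.65 FPKM (adjusted p = 2.31e-05). Myh11, the smooth muscle myosin heavy chain, was 7.75-fold higher at 22.7 ± 3.03 FPKM (adjusted p = 0.00117). Mylk, the kinase that activates smooth muscle myosin, was 4.59-fold higher at 123 ± 14.4 FPKM (log2 2.20 ± 0.24, adjusted p = 0.000698, and log2 1.40 with melanocyte RNA subtracted). The member that was lower in sheath was Des, the muscle intermediate filament desmin (1.19 ± 1.15 against 8.36 ± 3.56 FPKM). Calcium handling genes split, with 5 of 23 higher and 3 lower, as adjusted over the list alone (camera adjusted p = 0.0621). Itpr1, an intracellular calcium release channel, was 5.63-fold higher at 22.9 ± 2.84 FPKM.

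Endothelin receptors were abundant in dermal sheath. Ednra (chromosome 8, 77663031 to 77724464) reached 232 ± 55.4 FPKM against 23.9 ± 4.77 in fibroblasts (9.30-fold, log2 3.22 ± 0.27, adjusted p = 0.000208). Ednrb (chromosome 14, 103814625 to 103844402) reached 984 ± 408 against 119.9 ± 24.9 FPKM (7.87-fold, log2 2.98 ± 0.34, adjusted p = 0.000876). With melanocyte RNA subtracted from the fibroblast libraries it stood at log2 9.88. Its fibroblast level was below the subtracted share of its melanocyte level and was set to 0, so log2 9.88 only restates the sheath level. The list of vasoactive receptors to which both genes belong went both ways. It gave 5 of 21 members higher and 4 lower, or 8 and 4 adjusted over the list alone (camera adjusted p = 0.0916, and adjusted p = 0.00202 with fry). Integrin and focal adhesion genes were higher as a group (10 of 22 higher, 2 lower, or 11 and 3 adjusted over the list alone, camera adjusted p = 6.75e-05, and adjusted p = 0.121 with an estimated correlation and 0.0978 with melanocyte RNA subtracted). Itga8, the integrin alpha 8 chain, was 10.1-fold higher at 24.5 ± 10.7 FPKM, and Itga11 was 6.74-fold higher. Vcl, the focal adhesion protein vinculin, was 7.11-fold higher.

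The list of insulin-like and platelet-derived growth factor (IGF and PDGF) genes was higher in sheath, with 8 of 15 members higher and 0 lower, or 9 and 0 adjusted over the list alone (camera adjusted p = 4.11e-06, and adjusted p = 0.114 with an estimated correlation and 0.065 with melanocyte RNA subtracted). Its leading members were binding proteins, with Igfbp4 55.1-fold higher at 1133 ± 254 FPKM, Igfbp7 43.8-fold and Igfbp3 26.6-fold. Pdgfra, a receptor of dermal mesenchyme, was 3.24-fold higher at 207 ± 41.3 FPKM (adjusted p = 0.00337, and 0.122 with melanocyte RNA subtracted). Pdgfrb was at 47.6 ± 11.9 against 30.5 ± 2.53 FPKM and was not called (adjusted p = 0.206). Genes listed for the dermal papilla were also higher in sheath than in fibroblasts, 13 of 26 with 2 lower, or 15 and 2 adjusted over the list alone (camera adjusted p = 4.11e-06, and adjusted p = 0.270 with an estimated correlation and 0.065 with melanocyte RNA subtracted). Corin, a serine protease of the papilla, was 41.1-fold higher at 84.2 ± 31.5 FPKM. Alpl, tissue-nonspecific alkaline phosphatase, was 6.07-fold higher at 19.1 ± 2.73 FPKM. Sox2, a transcription factor of certain papillae, was low but 3.55-fold higher in sheath (2.84 ± 0.480 FPKM), and a pseudocount of 5 brought its log2 difference to 0.63, under the threshold of 1.

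Collagen and matrix genes changed in both directions. Of 27 fibrillar matrix genes, 10 were higher and 4 lower in sheath, or 10 and 5 adjusted over the list alone (camera adjusted p = 0.0251, and adjusted p = 0.472 with an estimated correlation and 0.0762 with quantile normalization). With melanocyte RNA subtracted the fibrillar matrix list pointed the other way (adjusted p = 0.065). Col11a1, a fibrillar collagen of cartilage and tendon, was 61.7-fold higher at 379 ± 61.5 FPKM, and Fmod, a proteoglycan of tendon, was 19.2-fold higher. No fold is given for 2 abundant members, both counted among the calls, that were listed at 0 in both libraries of a population. Both also entered the fibrillar matrix list test in every comparison, and no list test without them was run. Col3a1, type III collagen, was listed at 0 in both fibroblast libraries and at 1188 and 1395 FPKM in the sheath libraries. Sparc, a collagen-binding glycoprotein, was listed at 0 in both sheath libraries and at 7817 and 9367 FPKM in the fibroblast libraries. Basement membrane genes went both ways, with 11 of 24 higher and 3 lower, or 11 and 4 adjusted over the list alone (camera adjusted p = 0.0890). Higher members were Col4a2 (11.5-fold higher), Nid1 (11.3-fold higher) and Lamc3 (19.1-fold higher). Of the 22 dermal fibroblast genes, 4 were higher and 7 lower in sheath, or 5 and 7 adjusted over the list alone (camera adjusted p = 0.390). Dpp4, a surface peptidase of upper dermal fibroblasts, was 17.0-fold lower in sheath and Ccl11, the chemokine eotaxin, was 16.1-fold lower. Mfap5, a microfibril protein, was 14.9-fold higher. Dcn, the proteoglycan decorin, was 2.17-fold lower in sheath at 704 ± 171 against 1538 ± 428 FPKM (log2 -1.12 ± 0.27, adjusted p = 0.0290), a call that was lost without fibroblast replicate 2 (log2 -0.83, adjusted p = 0.203) or sheath replicate 1 (log2 -0.87, adjusted p = 0.183). Dcn was also not called, at the same log2, with no filter on low values (adjusted p = 0.0771) or with all 6 populations in the fit (adjusted p = 0.0563), and stood at log2 -1.98 with melanocyte RNA subtracted.

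WNT pathway genes were lower in dermal sheath than in fibroblasts, 13 of 28 with 4 higher, or 13 and 5 adjusted over the list alone (camera adjusted p = 0.0217, and adjusted p = 0.232 with an estimated correlation). Axin2, a direct target of beta-catenin, was 13.2-fold lower (3.32 ± 0.732 against 56.0 ± 8.63 FPKM), and Apcdd1, a membrane inhibitor of the pathway, was 9.07-fold lower. Lef1, a transcription factor of the pathway, was 4.28-fold lower (adjusted p = 0.000672). Axin2 and Lef1 were higher in melanocytes than in fibroblasts (69.4 ± 9.01 and 97.8 ± 29.9 FPKM), and Lef1 turned to log2 1.10 once melanocyte RNA was subtracted from the fibroblast libraries. For BMP signalling, 3 of 20 genes were higher and 3 lower, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.422). The antagonist Grem1 was 42.4-fold lower in sheath (88.4 ± 24.4 FPKM in fibroblasts) and the antagonist Nog 7.97-fold higher. FGF genes gave 4 of 16 higher and 2 lower, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.0621), led by Fgf18 (18.3-fold higher at 69.4 ± 7.87 FPKM). Hedgehog genes gave 4 of 10 higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.281), with Gli1 7.04-fold higher. TGF-beta genes gave 3 of 20 higher and 3 lower, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.134), with Ctgf 12.2-fold higher. Notch genes gave 4 of 13 higher and 0 lower, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.124), with Hes1 4.29-fold higher.

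Cell cycle genes were lower in dermal sheath as a group (median log2 -0.69, camera adjusted p = 4.51e-05, and adjusted p = 0.323 with an estimated correlation), although only 2 of 24 were called lower and 0 higher, also adjusted over the list alone. With melanocyte RNA subtracted the cell cycle list (adjusted p = 0.550) and the immediate early list (adjusted p = 0.783) pointed the other way. The called members were Mcm3 and Mcm5 of the replication helicase, 2.14-fold and 2.65-fold lower (log2 -1.10 ± 0.27 and -1.41 ± 0.26), and both lost their calls in fits without 1 library at similar folds. Mcm3 was at log2 -1.24 to -0.96 in the 6 fits (adjusted p = 0.0532 to 0.206), and Mcm5 at log2 -1.33 without sheath replicate 1 (adjusted p = 0.0504), -1.41 without fibroblast replicate 1 (0.0561) and -1.40 without fibroblast replicate 2 (0.0634). With a pseudocount of 5 their log2 differences were -0.77 and -0.88, and with melanocyte RNA subtracted neither was called (log2 -0.21 and -1.26, adjusted p = 0.798 and 0.0916). Mcm3 was also not called with the pair fitted alone (adjusted p = 0.0543). The proliferation marker Mki67, named after its values were seen, was at 15.3 ± 1.21 against 28.9 ± 3.97 FPKM, under the threshold of fold. Immediate early genes, which cell dissociation can induce, were higher in sheath (6 of 20 higher, 0 lower, or 6 and 1 adjusted over the list alone, camera adjusted p = 0.0165, and adjusted p = 0.481 with an estimated correlation, 0.0623 with quantile normalization and 0.0769 with fry). Klf4 was 4.29-fold and Nr4a1 3.10-fold higher.

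Between dermal sheath and dermal papilla, Acta2 was 25.8-fold higher in sheath (39.9 ± 13.8 FPKM in papilla, log2 4.69 ± 0.36, adjusted p = 0.000161). Tagln (chromosome 9, 45929619 to 45936058) was 17.2-fold higher (log2 4.10 ± 0.23, adjusted p = 7.16e-05). Tnmd (chromosome X, 133850980 to 133865577), the tendon membrane protein tenomodulin, was 46.5-fold higher at 522 ± 146 FPKM (adjusted p = 9.78e-05). In papilla, Rspo4 (chromosome 2, 151842927 to 151874668), a secreted amplifier of WNT signalling, reached 313 ± 16.9 FPKM, 53.7-fold higher than in sheath (log2 sheath minus papilla -5.75 ± 0.27, adjusted p = 6.77e-05). The gene a (nonagouti, chromosome 2, 154791402 to 155051012), which encodes the agouti signalling protein that papilla cells send to melanocytes, reached 152 ± 35.3 FPKM in papilla against 1.20 ± 0.538 in sheath (69.9-fold).

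In this comparison 1052 genes were higher and 999 lower in dermal sheath. Without papilla replicate 2 the counts were 700 and 480, and without papilla replicate 1 the count higher in papilla was 485, while a pseudocount of 5 left 468 genes higher in papilla. With genes at least as high in melanocytes as in fibroblasts left out before the fit, 609 genes were higher in papilla, and with melanocyte RNA subtracted from the fibroblast libraries the counts were 691 and 541. That subtraction leaves sheath and papilla values as they are, so here it acts only through the variance shared in the fit and the genes tested.

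Of the 22 contractile genes tested, 16 were higher in sheath than in papilla and 0 lower, also adjusted over the list alone (camera adjusted p = 1.22e-13, and adjusted p = 0.0908 with an estimated correlation). Casq2 was 36.8-fold, Actg2 29.5-fold and Mylk 12.7-fold higher, and Myh11 was 3.99-fold higher (adjusted p = 0.00734, and 0.0502 without papilla replicate 1). Vasoactive receptors were higher, 7 of 21 with 2 lower, also adjusted over the list alone (camera adjusted p = 0.0220, and adjusted p = 0.174 with an estimated correlation). Ednrb was 27.5-fold (adjusted p = 0.000125), Ednra 4.45-fold (adjusted p = 0.00127) and Agtr1a, the angiotensin II receptor, 6.00-fold higher. Integrin and focal adhesion genes gave 7 of 22 higher and 1 lower, or 10 and 1 adjusted over the list alone (camera adjusted p = 1.61e-04, and adjusted p = 0.0908 with an estimated correlation). Itgb3 was 20.1-fold and Itga11 19.7-fold higher in sheath, and Itga9 was 11.2-fold lower. Itga8 was not called (24.5 ± 10.7 against 18.1 ± 3.95 FPKM, adjusted p = 0.626). Calcium handling genes gave 3 of 23 higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.234).

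Fibrillar matrix genes were higher in sheath than in papilla, 21 of 27 with 1 lower, also adjusted over the list alone (camera adjusted p = 3.84e-17, and adjusted p = 0.0908 with an estimated correlation). Postn, the matricellular protein periostin, was 24.0-fold higher at 1664 ± 298 FPKM, and Col12a1 was 21.7-fold higher. Col1a1, the main chain of type I collagen, was 16.8-fold higher at 4985 ± 1396 against 299 ± 104 FPKM. The member called lower was Sparc, listed at 0 in both sheath libraries and at 1181 and 1063 FPKM in papilla. Dermal fibroblast genes gave 11 of 22 higher and 3 lower, or 12 and 3 adjusted over the list alone (camera adjusted p = 9.54e-04, and adjusted p = 0.224 with an estimated correlation). Mfap5 was 28.4-fold and Cxcl12 8.81-fold higher and Gpx3, a secreted glutathione peroxidase, 8.61-fold lower. Dcn was 7.00-fold higher in sheath (adjusted p = 0.000422). Lum was at 71.6 ± 29.0 against 32.9 ± 0.694 FPKM and was not called (adjusted p = 0.0904). IGF and PDGF genes gave 5 of 15 higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.00965, and adjusted p = 0.174 with an estimated correlation and 0.0707 with quantile normalization), led by Igfbp2 at 25.2-fold. Neither Pdgfra (log2 0.31 ± 0.26, adjusted p = 0.524) nor Pdgfrb (log2 -0.11 ± 0.27, adjusted p = 0.845) was called between sheath and papilla.

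**Figure D2:**
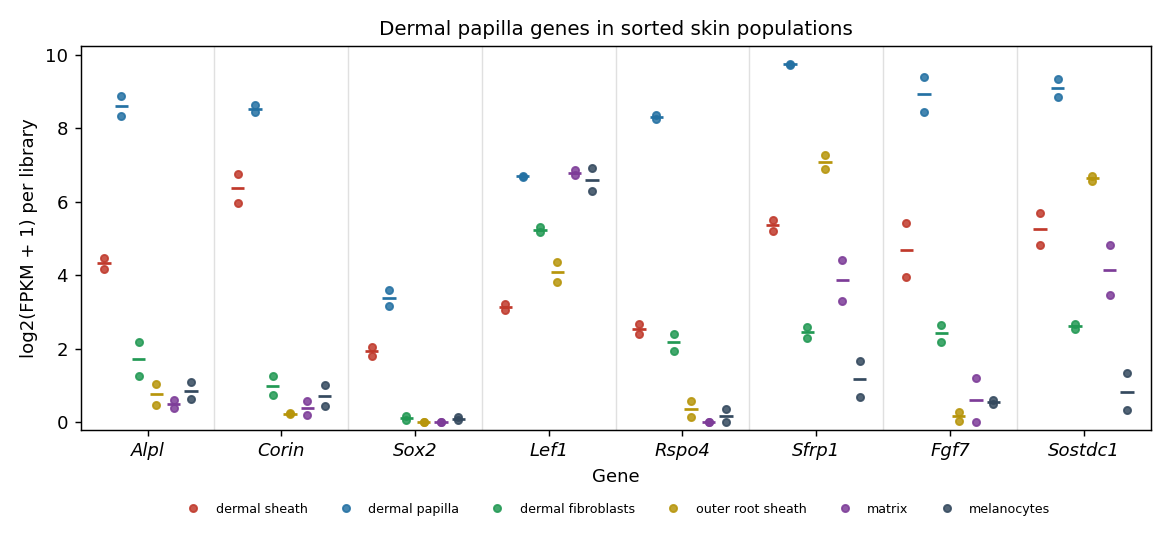
Log2(FPKM + 1) of dermal papilla genes in each library of the 6 sorted populations. Points are libraries and short lines are means of 2 libraries. Corin and Alpl were highest in dermal papilla (369 ± 36.0 and 395 ± 105 FPKM) and intermediate in dermal sheath (84.2 ± 31.5 and 19.1 ± 2.73 FPKM). Lef1 was as high in matrix (109.9 ± 6.61 FPKM) as in papilla (102 ± 2.02 FPKM).

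Of the 26 dermal papilla genes tested, 21 were lower in sheath than in papilla and 0 higher, or 22 and 0 adjusted over the list alone (camera adjusted p = 2.17e-17, and adjusted p = 0.0908 with an estimated correlation). Alpl (chromosome 4, 137741733 to 137796384) was 19.4-fold lower in sheath (adjusted p = 0.000229), and Notum, an enzyme that inactivates WNT proteins, was 31.7-fold lower. Fgf7, a growth factor for keratinocytes, was 18.9-fold lower (507 ± 224 FPKM in papilla). Corin was 4.49-fold lower in sheath (adjusted p = 0.00293). Sox2 was 2.73-fold lower in sheath (9.58 ± 2.28 FPKM in papilla, adjusted p = 0.0106), but was not called without papilla replicate 1 (adjusted p = 0.0773) or sheath replicate 1 (adjusted p = 0.0578). A pseudocount of 5 brought Sox2 from log2 -1.45 to -0.89, and with melanocyte RNA subtracted its adjusted p was 0.0501 at the same log2. BMP genes were lower in sheath, 13 of 20 with 0 higher, also adjusted over the list alone (camera adjusted p = 3.04e-07, and adjusted p = 0.0908 with an estimated correlation). Lower members were the ligand Bmp4 (15.1-fold), the antagonist Sostdc1 (14.1-fold) and the target Id2 (9.70-fold, adjusted p = 0.0954 with melanocyte RNA subtracted, at the same fold). Bmp4 and Sostdc1 are also on the papilla list, as are Wif1, Lef1, Fgf10 and Hey1 of the lists that follow. These list results are therefore not independent of the papilla list.

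WNT genes were lower in sheath than in papilla, 15 of 28 with 6 higher, or 16 and 6 adjusted over the list alone (camera adjusted p = 2.10e-04, and adjusted p = 0.0908 with an estimated correlation). The secreted inhibitors Sfrp1 (chromosome 8, 23411502 to 23449632) and Wif1 were 20.7-fold and 14.7-fold lower, from 848 ± 12.7 and 659.5 ± 0.0912 FPKM in papilla. Lef1 (chromosome 3, 131110471 to 131224356) was 11.7-fold lower (log2 -3.55 ± 0.23, adjusted p = 9.93e-05, and 0.134 with melanocyte RNA subtracted, at the same log2). FGF genes were lower in sheath, 8 of 16 with 1 higher, or 9 and 1 adjusted over the list alone (camera adjusted p = 9.13e-04, and adjusted p = 0.115 with an estimated correlation). Fgf10 was 8.47-fold lower and Fgf18 14.4-fold higher. Hedgehog genes gave 1 of 10 higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.0560). Notch genes gave 3 of 13 higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.420), with Hey1 11.1-fold lower and Hes1 6.79-fold higher. For TGF-beta signalling 6 of 20 genes were higher and 4 lower, or 6 and 5 adjusted over the list alone (camera adjusted p = 0.920), and the list's median (-0.17) and mean (-0.05) were negative while camera gave the upward direction. Basement membrane genes gave 7 of 24 higher and 2 lower, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.281), with a median of -0.04 against a mean of 0.26 and an upward test. Immediate early genes gave 5 of 20 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.535), with a median of -0.21 against a mean of 0.14 and an upward test. Cell cycle genes were lower as a group (median log2 -0.62, camera adjusted p = 0.00287, and adjusted p = 0.407 with an estimated correlation, 0.0540 with fry and 0.103 with melanocyte RNA subtracted, at the same sheath and papilla values), with 0 of 24 higher and 1 lower, or 0 and 0 adjusted over the list alone.

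Between dermal papilla and dermal fibroblasts, Corin (chromosome 5, 72300025 to 72504473) reached 369 ± 36.0 FPKM in papilla against 1.03 ± 0.507 in fibroblasts (185-fold, log2 7.53 ± 0.32, adjusted p = 1.66e-05). Sfrp1 was 156-fold higher (adjusted p = 1.03e-05). Scube1 (chromosome 15, 83604999 to 83725021), a secreted glycoprotein of the papilla, was 139-fold higher at 398 ± 26.6 FPKM, and Alpl was 118-fold higher. In fibroblasts, Col1a1 was at 5157 ± 1999 FPKM, 17.1-fold higher than in papilla (log2 papilla minus fibroblasts -4.09 ± 0.37, adjusted p = 0.000251), and Lum was 21.6-fold higher (adjusted p = 0.000152).

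Here 1057 genes were higher and 946 lower in papilla. The count higher in papilla was 525 without papilla replicate 1, 565 without papilla replicate 2 and 670 without fibroblast replicate 2. The count higher in fibroblasts was 607, 618, 510 and 493 without papilla replicate 1, papilla replicate 2, fibroblast replicate 1 and fibroblast replicate 2. A pseudocount of 5 gave 565 and 551 genes. Of the 946 genes higher in fibroblasts, 409 (43.2%) were at least as high in melanocytes as in fibroblasts, against 51.1% of all tested genes. Leaving such genes out before the fit gave 560 genes higher in fibroblasts, and subtracting melanocyte RNA gave 2223 genes higher in papilla.

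Of the 26 papilla genes tested, 24 were higher in papilla than in fibroblasts and 0 lower, also adjusted over the list alone (camera adjusted p = 2.85e-26, and adjusted p = 0.144 with an estimated correlation). Fgf7 was 89.7-fold and Sostdc1 89.3-fold higher, Sox2 was 9.71-fold higher (adjusted p = 0.000226), and Lef1 was 2.74-fold higher (log2 1.45 ± 0.23, adjusted p = 0.00372, and log2 4.65 with melanocyte RNA subtracted). BMP genes were higher in papilla, 11 of 20 with 1 lower, also adjusted over the list alone (camera adjusted p = 1.55e-05, and adjusted p = 0.153 with an estimated correlation), the member that was lower being Grem1 (12.8-fold). FGF genes were higher, 8 of 16 with 2 lower, or 9 and 2 adjusted over the list alone (camera adjusted p = 5.19e-05, and adjusted p = 0.153 with an estimated correlation). Fgf10 was 67.8-fold and the receptor Fgfr3 9.70-fold higher. Hedgehog genes were higher, 5 of 10 with 2 lower, also adjusted over the list alone (camera adjusted p = 0.0209, and adjusted p = 0.263 with an estimated correlation and 0.511 with melanocyte RNA subtracted). The targets Hhip (63.6-fold) and Ptch1 (13.7-fold) were higher, whereas the co-receptor Cdon was 18.0-fold lower. WNT genes gave 10 of 28 higher and 6 lower, or 10 and 7 adjusted over the list alone (camera adjusted p = 0.215, and adjusted p = 1.17e-04 with fry). The inhibitor Sfrp1 led (156-fold) before the R-spondins Rspo4 (69.1-fold), Rspo2 (67.0-fold) and Rspo3 (28.2-fold). Notch genes gave 4 of 13 higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.123). TGF-beta genes gave 6 of 20 higher and 6 lower, also adjusted over the list alone (camera adjusted p = 0.500), with Inhba, an activin subunit, 29.6-fold higher. IGF and PDGF genes gave 7 of 15 higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.0577). Sostdc1, Fgf7, Fgf10, Hhip, Rspo2, Rspo3 and Inhba are also on the papilla list, so results of their signalling lists are not independent of it.

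Fibrillar matrix genes were lower in papilla than in fibroblasts, 20 of 27 with 3 higher, also adjusted over the list alone (camera adjusted p = 1.25e-09, and adjusted p = 0.201 with an estimated correlation). Thbs2 was 26.6-fold and Fn1, fibronectin, 15.7-fold lower, and Col3a1 was among those called higher because fibroblasts were listed at 0. Fibroblast genes were lower, 11 of 22 with 3 higher, also adjusted over the list alone (camera adjusted p = 1.55e-05, and adjusted p = 0.212 with an estimated correlation). Cd34 was 18.1-fold and Dcn 15.2-fold lower (adjusted p = 4.94e-05 and 8.94e-05) and Gpx3 33.1-fold higher. Contractile genes were divided in papilla, 9 of 22 being higher and 3 lower than in fibroblasts, or 9 and 4 adjusted over the list alone. The camera adjusted p was 0.0255, with 0.219 under an estimated correlation and 0.0535 under a replicate block. With melanocyte RNA subtracted the contractile list pointed the other way (adjusted p = 0.874). Acta2 was 5.08-fold higher in papilla (adjusted p = 0.00338) and Mylk 2.76-fold lower (log2 -1.46 ± 0.24, adjusted p = 0.00476, and log2 -2.26 with melanocyte RNA subtracted), and neither Tagln (log2 0.42 ± 0.23, adjusted p = 0.304) nor Myh11 (log2 0.96 ± 0.36, adjusted p = 0.128) was called. Itga8 was 7.86-fold higher in papilla (adjusted p = 0.00158), while integrin and focal adhesion genes gave 6 of 22 higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.717).

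Vasoactive receptors gave 3 of 21 higher and 5 lower in papilla than in fibroblasts, or 3 and 6 adjusted over the list alone (camera adjusted p = 0.500), with a median log2 of 0.11 against a mean of -0.09 and a downward test. Ednrb was 3.49-fold lower in papilla (adjusted p = 0.00904), a call lost without papilla replicate 1. It turned to higher in papilla, at log2 5.10, once melanocyte RNA was subtracted, which set its fibroblast values to 0. Ednra was 2.09-fold higher in papilla (adjusted p = 0.0301), a call lost without either papilla library (adjusted p = 0.0844 without replicate 1 and 0.156 without replicate 2) or either fibroblast library (0.190 and 0.0542). Ednra was also not called with a pseudocount of 5 (log2 0.95), no filter on low values (adjusted p = 0.0530) or melanocyte RNA subtracted (0.531). Pdgfra was 2.62-fold higher in papilla (adjusted p = 0.00860, but 0.0588 without papilla replicate 2, 0.0571 without fibroblast replicate 1 and 0.275 with melanocyte RNA subtracted). Pdgfrb was not called (log2 0.72 ± 0.27, adjusted p = 0.123). Basement membrane genes gave 8 of 24 higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.594), with a median log2 of -0.14 against a mean of 0.35 and an upward test. Calcium handling genes gave 5 of 23 higher and 4 lower and cell cycle genes 0 of 24 in either direction, with the same counts adjusted over the list alone (camera adjusted p = 0.594 and 0.329). Immediate early genes there gave 5 of 20 higher and 1 lower, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.123).

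**Figure D3:**
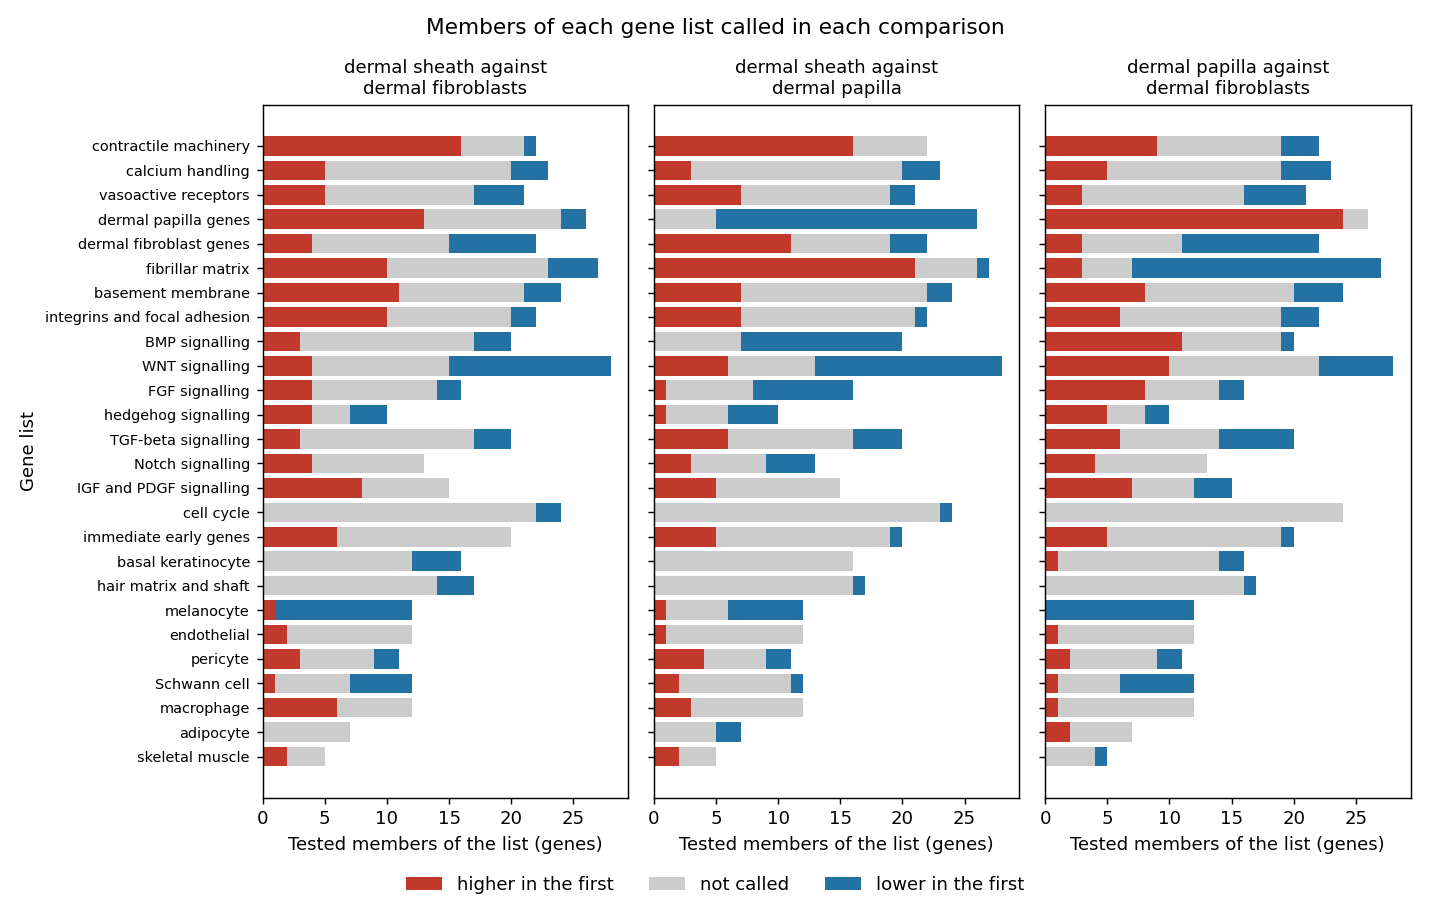
Number of tested genes of each list reported, on the horizontal axis, called higher in the first population, lower in it or not called, for the 3 comparisons of dermal populations. Of 22 contractile genes, 16 were higher in dermal sheath against dermal fibroblasts and 16 against dermal papilla, and of 12 melanocyte genes 11 and 12 were higher in fibroblasts than in sheath and papilla.

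Genes higher in dermal sheath than in both other populations numbered 621, against 79.5 for independent lists and a mean of 0.13 (highest 1) in 100 simulations of unchanged groups sharing the sheath libraries. These simulations hold no effects, so they do not measure how much overlap shared libraries give between lists of this size. Part of each excess may come from the shared libraries, which were too few to split. Thbs4, a matricellular protein of tendon and muscle, led the set after Tnmd at 156 ± 16.8 FPKM, 41.0-fold higher than in papilla and 69.7-fold higher than in fibroblasts. Prelp, a proteoglycan that anchors basement membranes, was 34.2-fold and 33.8-fold higher, Tnnt2, the cardiac troponin T, 44.1-fold and 31.1-fold, and Stmn2, a microtubule regulator best known in neurons, 33.4-fold and 39.4-fold. Casq2, Actg2, Acta2, Cpxm2 and Clic5 were also among the 10 leading genes. Without sheath replicate 1 the set held 404 genes, and with melanocyte RNA subtracted 384.

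Genes higher in dermal papilla than in both others numbered 635 (79.9 for independent lists, simulated mean 0.15, highest 2). The gene a, Rspo4 and Scube1 led, followed by Lypd1 (90.5 ± 4.92 FPKM) and Prss12, a serine protease (403 ± 52.0 FPKM). Mc5r, a melanocortin receptor, was at 147 ± 3.56 FPKM, 65.7-fold above fibroblasts, and Dio2, the deiodinase that activates thyroid hormone, at 159 ± 55.2 FPKM, 78.8-fold above fibroblasts. Without papilla replicate 1 or 2 the set held 279 or 283 genes, a pseudocount of 5 gave 331 and subtracting melanocyte RNA 395. Sheath and papilla shared 297 genes higher than in fibroblasts (79.9 for independent lists, simulated mean 0.15, highest 2), Corin and Igfbp3 among them. This set held 195 or 174 genes without fibroblast replicate 1 or 2, 141 with a pseudocount of 5 and 1218 with melanocyte RNA subtracted.

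Genes higher in dermal fibroblasts than in both others numbered 521 (62.5 for independent lists, simulated mean 0.16, highest 3). The 10 that led were Mir211, Ptgds, Dct, Mlana, Tyrp1, Trpm1, Pmel, Npy, Slc45a2 and Tyr, all of them abundant in the melanocyte libraries. Once melanocyte RNA was subtracted, Ptgds, Trpm1, Slc45a2 and Tyr turned to lower in fibroblasts than in sheath (log2 sheath minus fibroblasts 1.62, 1.25, 1.47 and 1.73). Their fibroblast levels lay below the subtracted share of their melanocyte levels and were set to 0. Pmel was not called against sheath under that setting (adjusted p = 0.850). Without fibroblast replicate 1 or 2 the set held 240 or 230 genes, and a pseudocount of 5 gave 298. Of this set, 285 genes (54.7%) were at least as high in melanocytes as in fibroblasts, against 51.1% of all tested genes. With all such genes left out before the fit, 245 genes were called in the set. Leading genes low in melanocytes, chosen after their values were seen, were Tac1, the substance P precursor (65.4 ± 15.3 FPKM in fibroblasts and 0.121 ± 0.172 in melanocytes), C1qtnf3 (183 ± 72.1 FPKM) and Fgfr4 (48.8 ± 9.51 FPKM). Tac1 was 58.9-fold higher in fibroblasts than in sheath and 40.9-fold higher than in papilla, and C1qtnf3 was 33.9-fold and 28.9-fold higher.

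Melanocyte genes separated the fibroblast libraries from the other dermal libraries. Dct (chromosome 14, 118012790 to 118052244), a melanin synthesis enzyme, reached 1774 ± 146 FPKM in fibroblasts, 80.7-fold above papilla, against 6.01 ± 1.78 in sheath and 3181 ± 1249 in melanocytes. Mlana (chromosome 19, 29697824 to 29708634), a melanosome protein, reached 3254 ± 162 FPKM in fibroblasts and 5036 ± 5.06 in melanocytes. Of 12 melanocyte genes, 11 were lower in sheath than in fibroblasts and 1, Ednrb, was higher (camera adjusted p = 5.10e-16, and adjusted p = 0.0477 with an estimated correlation and 0.777 with melanocyte RNA subtracted). All 12 were lower in papilla than in fibroblasts (camera adjusted p = 1.26e-19, and adjusted p = 0.0599 with an estimated correlation), both with the same counts adjusted over the list alone. With melanocyte RNA subtracted the melanocyte list in papilla against fibroblasts pointed the other way (adjusted p = 0.977). The share subtracted was the median over 11 of these 12 genes, so the list's loss under that setting was set in advance. Between sheath and papilla, 1 was higher and 6 lower in sheath, or 1 and 7 adjusted over the list alone (camera adjusted p = 0.0154, and adjusted p = 0.174 with an estimated correlation and 0.0779 with melanocyte RNA subtracted, at the same sheath and papilla values). Mir211, a microRNA within Trpm1, was listed at 0 in the sheath and papilla libraries, at 1818 and 726 FPKM in the fibroblast libraries, and at 11796 and 7750 FPKM in the melanocyte libraries. Schwann cell genes, some of them shared with melanocytes, were lower in papilla than in fibroblasts (6 of 12, 1 higher, also adjusted over the list alone, camera adjusted p = 0.00552, and adjusted p = 0.201 with an estimated correlation and 0.0723 with melanocyte RNA subtracted). Sox10 was 20.3-fold lower, and not called with melanocyte RNA subtracted (adjusted p = 0.552). Against fibroblasts, sheath gave 1 of 12 higher and 5 lower (camera adjusted p = 0.0588), and against papilla 2 higher and 1 lower (camera adjusted p = 0.605, with a median of -0.06 against a mean of 0.08), also adjusted over the list alone.

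**Figure D4:**
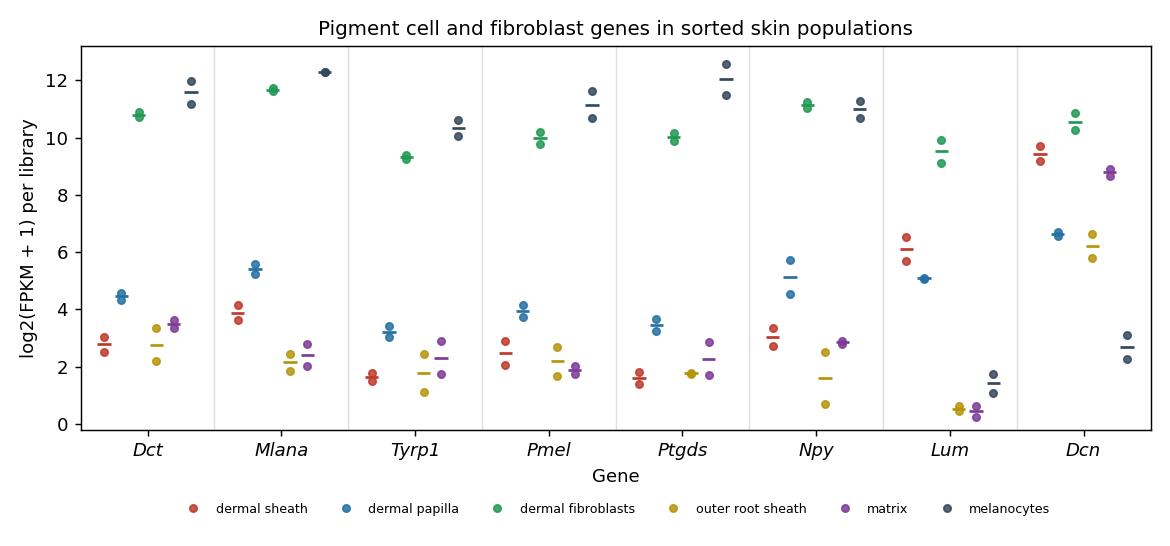
Log2(FPKM + 1) of pigment cell genes (Dct, Mlana, Tyrp1, Pmel), of Ptgds and Npy, and of the fibroblast genes Lum and Dcn in each library of the 6 sorted populations. Points are libraries and short lines are means of 2 libraries. Mlana stood at 3254 ± 162 FPKM in dermal fibroblasts against 14.1 ± 3.66 in dermal sheath, and Lum at 759 ± 284 in fibroblasts against 1.74 ± 0.876 in melanocytes.

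Macrophage genes were low in all dermal populations and higher in sheath than in fibroblasts (6 of 12, 0 lower, or 8 and 0 adjusted over the list alone, camera adjusted p = 9.17e-06, and adjusted p = 0.200 with an estimated correlation). They were also higher than in papilla (3 of 12, 0 lower, also adjusted over the list alone, camera adjusted p = 0.00832, and adjusted p = 0.240 with an estimated correlation). Tyrobp, an immune adaptor, was at 14.5 ± 2.45 FPKM in sheath, 3.41 ± 1.21 in papilla and 3.44 ± 0.190 in fibroblasts, and was not called against fibroblasts with melanocyte RNA subtracted (adjusted p = 0.103). Papilla against fibroblasts gave 1 of 12 higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.0386). The adjusted p was 0.378 with an estimated correlation, 0.0529 with fry, 0.0646 with a replicate block and 0.604 with melanocyte RNA subtracted. Pericyte genes went both ways beside the contractile genes, with 3 of 11 higher and 2 lower in sheath than in fibroblasts, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.0747). Against papilla 4 were higher and 2 lower in sheath, also adjusted over the list alone (camera adjusted p = 0.535, with a median of -0.23 against a mean of 0.39). Papilla against fibroblasts gave 2 pericyte genes higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.989). Mcam was at 119 ± 7.65 FPKM in sheath, 9.19-fold above fibroblasts, Kcnj8 was 6.31-fold lower in sheath, and the pericyte marker Rgs5, named after its values were seen, was at 13.9 ± 0.735 FPKM in sheath, 6.06 ± 1.41 in papilla and 11.2 ± 2.77 in fibroblasts. Rgs5 was 2.13-fold higher in sheath than in papilla (log2 1.09 ± 0.30, adjusted p = 0.0416), a call lost without either sheath library (log2 1.14 and 1.04, adjusted p = 0.120 and 0.140) or either papilla library (log2 0.89 and 1.30, adjusted p = 0.237 and 0.0861). It was also not called with a pseudocount of 5 (log2 0.78) or, at the same log2, with no filter on low values (adjusted p = 0.0686) or melanocyte RNA subtracted (0.186).

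Endothelial genes were mostly low, with 2 of 12 higher and 0 lower in sheath than in fibroblasts (camera adjusted p = 0.0621) and 1 higher and 0 lower than in papilla (camera adjusted p = 0.535). Papilla had 1 endothelial gene higher and 0 lower than fibroblasts (camera adjusted p = 0.0209, and adjusted p = 0.623 with an estimated correlation, 0.121 with fry and 0.174 with melanocyte RNA subtracted), all with the same counts adjusted over the list alone. The member higher in papilla was Sox18, a transcription factor also known in papilla development (173 ± 119 FPKM). Basal keratinocyte genes were lower in sheath than in fibroblasts (0 of 16 higher, 4 lower, or 0 and 5 adjusted over the list alone, camera adjusted p = 0.0472, and adjusted p = 0.486 with an estimated correlation and 0.124 with fry). The cadherins Cdh3 and Cdh1 were among them and were also high in melanocytes (157 ± 37.1 and 103 ± 27.5 FPKM). Their log2 differences from fibroblasts changed sign once melanocyte RNA was subtracted, to 0.72 (Cdh3, under the threshold of 1) and 2.90 (Cdh1). Against papilla the counts were 0 and 0 (camera adjusted p = 0.137). Papilla against fibroblasts gave 1 basal gene higher and 2 lower (camera adjusted p = 0.500, with a median of 0.12 against a mean of -0.23 and a downward test), both also adjusted over the list alone. The gene higher was Krt15 (log2 1.05, adjusted p = 0.0490), which was not called in 14 of 21 alternatives, with adjusted p = 0.312 without papilla replicate 1 (log2 0.71) and 0.428 with melanocyte RNA subtracted (log2 0.43). The 2 lower were Cdh3 and Cdh1, whose log2 differences changed sign, to 1.26 and 2.93, with melanocyte RNA subtracted. The keratin Krt5, named after its values were seen, was at 58.3 ± 19.3, 95.5 ± 36.0 and 68.9 ± 23.8 FPKM in sheath, papilla and fibroblasts against 2403 ± 23.9 in outer root sheath. Hair matrix and shaft genes were lower in sheath than in fibroblasts (0 of 17 higher, 3 lower, or 0 and 4 adjusted over the list alone, camera adjusted p = 0.00422, and adjusted p = 0.481 with an estimated correlation and 0.122 with fry). They were also lower than in papilla (0 higher, 1 lower, or 0 and 4 adjusted over the list alone, camera adjusted p = 2.51e-04, and adjusted p = 0.402 with an estimated correlation and 0.0767 with fry). Hoxc13 was 4.52-fold below fibroblasts and Msx2 6.85-fold below papilla. Papilla against fibroblasts gave 0 higher and 1 lower, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.500).

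Adipocyte genes gave 0 of 7 called in sheath against fibroblasts (camera adjusted p = 0.0621) and 2 higher and 0 lower in papilla against fibroblasts (camera adjusted p = 0.0861), also adjusted over the list alone. Sheath had 0 adipocyte genes higher and 2 lower than papilla, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.733). Cebpa, a regulator of adipocyte genes, was at 192 ± 68.2 FPKM in papilla and 20.2 ± 3.88 in sheath. Skeletal muscle genes gave 2 of 5 higher and 0 lower in sheath than in fibroblasts (camera adjusted p = 0.390) and than in papilla (camera adjusted p = 0.0135, and adjusted p = 0.174 with an estimated correlation). Papilla had 0 muscle genes higher and 1 lower than fibroblasts (camera adjusted p = 0.207), also adjusted over the list alone. The 2 genes, Tnnc2 and Acta1, were low in sheath (3.46 ± 0.697 and 1.23 ± 0.0662 FPKM), and with a pseudocount of 5 their log2 differences from fibroblasts were 0.67 and 0.29. Tnnc2 was not called against fibroblasts without fibroblast replicate 1 (adjusted p = 0.0710) or against papilla without papilla replicate 2 (0.102). Acta1 was not called against fibroblasts without fibroblast replicate 1 or 2 (0.156 and 0.119) or against papilla without papilla replicate 1 or 2 (0.116 and 0.0594). Tnnc2 was not called against fibroblasts (0.0634) or, at the same fold, papilla (0.0902) with melanocyte RNA subtracted, nor was Acta1 against fibroblasts (log2 0.91). The mast cell and lymphocyte list had 4 tested members and the erythroid list 1, too few for a test of the list, and 0 of them were called in any comparison, also adjusted over the list alone.

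The remaining sorted populations are described by their levels. Krt15, a keratin of basal and stem cells, was at 819 ± 34.1 FPKM in outer root sheath against 101 ± 25.3 in matrix. Trp63, a transcription factor of basal epithelium, was at 359 ± 9.50 FPKM in outer root sheath. Hoxc13, a regulator of hair keratins, was at 88.1 ± 0.574 FPKM in matrix and 43.3 ± 7.47 in outer root sheath. In melanocytes, Tyr reached 1454 ± 303 FPKM and Trpm1 1338 ± 138 FPKM, against 4.21 ± 1.41 and 1.86 ± 0.547 FPKM in matrix. Outer root sheath held Acta2 at 47.9 ± 15.8 FPKM and Tagln at 64.0 ± 17.0 FPKM, and matrix held Dcn at 444 ± 52.9 FPKM.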

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

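Both tests of GC content and of low genes were written before their result was seen, and the alternatives that left out genes or subtracted melanocyte RNA were chosen after the data were seen. Leaving out 1 library at a time moved the counts as follows: higher in sheath than fibroblasts 999 (676 to 966), higher in fibroblasts than sheath 873 (422 to 834), higher in sheath than papilla 1052 (700 to 1048), and higher in papilla than sheath 999 (480 to 994). It gave 1057 (525 to 1115) higher in papilla than fibroblasts, 946 (493 to 1002) higher in fibroblasts than papilla, 621 (404 to 485) higher in sheath than in both others, 635 (279 to 543) in papilla, 521 (230 to 470) in fibroblasts, and 297 (174 to 252) shared by sheath and papilla. Fewer libraries leave fewer degrees of freedom. A pseudocount of 5, which shrinks differences of low genes by construction, gave 658 and 442 for sheath and fibroblasts, 468 for papilla over sheath, 565 and 551 for papilla and fibroblasts, 331 and 298 for the papilla and fibroblast sets, and 141 for the shared set. A filter of at least 5 FPKM gave 578 genes higher in fibroblasts than in sheath, fewer genes being tested. With genes as high in melanocytes left out, fewer genes were tested, and 417 were higher in fibroblasts than sheath, 609 in papilla than sheath, 560 in fibroblasts than papilla and 245 in fibroblasts than both.

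Subtracting melanocyte RNA gave 1795 genes higher in sheath than fibroblasts, 691 in sheath than papilla, 541 in papilla than sheath and 2223 in papilla than fibroblasts, with 384, 395 and 1218 in the sheath, papilla and shared sets. Sheath and papilla values are left as they are, so between these 2 it acts only through the variance shared in the fit and the genes tested. By construction it takes the same share from every gene and sets negative values to 0, then scales up what is left, so genes absent from melanocytes rise in fibroblasts. The markers' own ratios ran from 18.7% (Tyr) to 72.7% (Dct), so it overcorrects genes of low ratio. The subtracted shares were 37.2% and 51.8%, while 19 other genes restricted to melanocytes had a median ratio of 26.9% (upper quartile 39.3%). Most of these 19 genes thus lay below both shares, and the subtraction tends to overcorrect such genes. Subtracting melanocyte RNA was the only alternative under which a called difference changed sign. Such a difference was not always called the other way, as 0.18 for Tcf7, 0.72 for Cdh3 and 0.89 for Pmel lie under the threshold of 1. Sheath minus fibroblasts became 1.62 for Ptgds, 1.25 for Trpm1, 1.47 for Slc45a2, 1.73 for Tyr, 0.18 for Tcf7, 2.28 for Etv5, 0.72 for Cdh3, 2.90 for Cdh1, 3.26 for Dst and 1.10 for Lef1. Papilla minus fibroblasts became 3.46 for Ptgds, 2.34 for Trpm1, 0.89 for Pmel, 2.58 for Slc45a2, 2.54 for Tyr, 1.26 for Cdh3, 2.93 for Cdh1, 5.10 for Ednrb and 1.25 for Npnt. Lists that turned in sheath against fibroblasts were fibrillar matrix (adjusted p = 0.065), cell cycle (0.550) and immediate early genes (0.783). In papilla against fibroblasts they were contractile machinery (0.874) and melanocyte (0.977). The melanocyte list's own members set the share, so its change was set in advance.

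Of 339 calls of named genes, 35 were lost with a pseudocount of 5, 15 with no filter, 5 with a pseudocount of 0.1, and 13 to 24 without 1 library, and the other settings fixed beforehand lost at most 4. Fits without 1 library tested fewer of these genes, so their losses are out of 335 or 329 calls, and those with the 5 FPKM filter out of 322. Subtracting melanocyte RNA lost 38 of 337 calls and changed the sign of 19 more, not all of which were called in the new direction. Of 81 list results, 37 were weaker with an estimated correlation, and only a list called in the main test can become weaker. The calls left were contractile machinery and melanocyte genes in sheath against fibroblasts (adjusted p = 0.0477 each). With fry 7 were weaker and 19 stronger, among the latter WNT genes in papilla against fibroblasts (1.17e-04). Vasoactive receptors (0.00202) and adipocyte genes (1.96e-04) in sheath against fibroblasts were others. Quantile normalization made 4 weaker and 4 stronger, among the latter immediate early genes in papilla against fibroblasts (0.0368). A pseudocount of 0.1 moved 0. Melanocyte RNA subtracted left 10 weaker and 2 stronger besides the 5 reversed. The 2 were dermal fibroblast genes in sheath against fibroblasts (adjusted p = 5.59e-04) and hedgehog genes in sheath against papilla (0.0322). The causes of these list changes were not tested. The planned count test was not run because whole reads could not be recovered, and unknown depth leaves the precision of low values unmeasured.

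Libraries that share a replicate number deviated together, with correlations of 0.505 to 0.557 among dermal populations and 0.196 to 0.557 over all 15 pairs. A replicate block raised every count, none by over 1.5 times. Genes higher in sheath than in fibroblasts rose from 999 to 1178, and those higher in fibroblasts than in sheath from 873 to 1071. The block ended 0 of the 339 named calls. Of 81 list results it ended 2 calls, the contractile machinery (adjusted p = 0.0535) and macrophage (0.0646) lists in papilla against fibroblasts. It added 6, among them the endothelial, pericyte and adipocyte lists in sheath against fibroblasts (0.0472 each) and the hedgehog (0.0293) and basal keratinocyte (0.0472) lists in sheath against papilla, and changed no other list call. Transcript GC content could account for part of it: taking out the GC trend left 48.6% of the mean correlation (0.332 to 0.162). Short RNAs and low genes did not, since 154% of it was left among genes of at least 10 FPKM.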

Other observations

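The comparison of outer root sheath with matrix and the 3 tests of pigment cell genes were chosen after results had been seen. Outer root sheath, the outer epithelial layer of the follicle, carried contractile genes at levels above the matrix. Acta2 was at 47.9 ± 15.8 FPKM in outer root sheath against 2.88 ± 0.636 in matrix (12.3-fold, limma with Benjamini-Hochberg adjusted p = 0.000244), Tagln was at 64.0 ± 17.0 against 4.88 ± 1.12 FPKM, and Myl9, a myosin light chain, was 9.44-fold higher. Of 22 contractile genes 9 were higher and 0 lower (camera adjusted p = 2.61e-09, and adjusted p = 0.00881 with an estimated correlation). Integrin genes (10 of 23 higher, 0 lower, adjusted p = 2.23e-09, and adjusted p = 0.00881 with an estimated correlation) and TGF-beta genes (12 of 20 higher, 0 lower, adjusted p = 6.55e-11, and adjusted p = 0.0461 with an estimated correlation) were higher as well, with Tgfb3 7.19-fold higher. Fibrillar matrix genes were also higher (7 of 27, 0 lower, adjusted p = 2.74e-04, and adjusted p = 0.137 with an estimated correlation), Col14a1 being 7.29-fold and Postn 6.94-fold higher, while Col1a1 was low in both (1.57 ± 0.558 and 1.75 ± 0.340 FPKM) and not called. Dermal fibroblast genes gave 4 of 22 higher and 1 lower (adjusted p = 0.212), with Cxcl12 4.84-fold higher and Dcn 6.01-fold lower at 76.0 ± 31.2 against 444 ± 52.9 FPKM. The stem cell receptor Lgr5 was 11.3-fold higher at 97.8 ± 5.44 FPKM. In all, 642 genes were higher and 351 lower in outer root sheath of 13974 tested. Matrix held more Krt35, a hair keratin, at 117 ± 21.2 FPKM (28.9-fold), Shh, a signal to the papilla, at 47.9 ± 5.19 FPKM (12.3-fold), and Lef1 at 109.9 ± 6.61 FPKM (6.53-fold). Hair matrix and shaft genes were lower in outer root sheath (12 of 17, 0 higher, adjusted p = 1.07e-13, and adjusted p = 0.0598 with an estimated correlation).

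Pigment cell genes were abundant in both dermal fibroblast libraries. Of 19 other genes with at least 100 FPKM in melanocytes and at least 20 times their level in each of sheath, papilla, outer root sheath and matrix, 100% lay at 10% or more of their melanocyte level in both fibroblast libraries, with a median of 26.9% and a range of 15.3% to 109%. This fits melanocyte-lineage cells or their RNA in the fibroblast sort. Carry-over of sorted melanocyte material at 1 share was also tested. No share lay in the ranges of ratios of over 5 of 11 pigment cell markers, which leaves 54.5% out. Tyr ranged from 13.9% to 30.7% and Mlana from 62.3% to 66.9%. Ranges from 2 libraries per population can miss a share that all markers hold, so this test cannot exclude carry-over at 1 share. Expression of these genes by fibroblasts themselves was not tested. An exchange of columns was excluded, because the 22 fibroblast genes were higher in fibroblasts than in melanocytes (median log2 difference 4.85, 21 of 22 higher).

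Some abundant genes were listed at 0 in both libraries of a dermal population. Malat1, a nuclear RNA of nearly all cells, was listed at 0 in all 6 dermal libraries and at 2634 and 4217 FPKM in outer root sheath. Short RNAs left out, of 249 protein-coding and long intergenic noncoding RNA genes reaching 500 FPKM in some library, 3 lay at exactly 0 in both libraries of a dermal population: Malat1 in all 3 populations, Sparc in sheath and Col3a1 in fibroblasts. Among the 249 genes, 5 pairs of gene and population lay at exactly 0. In 0 pairs did both libraries lie above 0 and below 0.1 FPKM. Whether the transcripts were absent or the values were entered as 0 for another reason was not tested.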
